A study of Mus musculus with 16 samples.

How the data were processed

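The series covers 4 kinds of sample from mouse: ChIP and input DNA of K1-ER and K1-NanER cells, 4sU-labelled RNA of K1-ER, K1-NanER and K1 cells, and polyadenylated RNA of fetal liver. Cells were treated with 200 nM 4-hydroxytamoxifen, for 3 h before fixation with 1% formaldehyde in the ChIP experiment, and 4sU was given at 500 uM for 1 h. Chromatin was sheared to 200 to 400 bp. Per the labels, 3 replicates were pooled before each ChIP library was made, so each factor has 1 library. The K1 column of the 4sU table does not name tamoxifen in its header, while the labels of the K1 samples give the same treatment as the other lines.

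The files used were the authors' processed tables: 1 table of 4sU genes, 1 table of fetal liver genes and 1 annotated peak list per factor. The submitters' processing notes name TopHat2 2.0.10, MACS 1.4.2 and build mm9. The program behind the expression levels and their q values, and the step that gave each peak its gene and motif, are not given in the sources used here. Expression is in FPKM, given by the authors as 1 value per group. The deposited log2 fold change is the test group over the reference, and recomputing it from the FPKM columns gave differences of at most 1.43e-09 in the 4sU table and, with liver levels under 0.1 raised to 0.1, of at most 0.0661 in the liver table. Each p-value and q value is that of the authors' own comparison, and the smallest p-value in the deposited tables is 5e-05, shared by 373 genes of K1-ER, 451 of K1-NanER and 284 of liver. In the 4sU table a level of 0 appears as 0.1 FPKM, which is called the floor here (101 genes in K1, 29 in K1-ER and 8 in K1-NanER). The fold enrichment of a peak is the authors' ratio of ChIP over input, and none lies under 30.0 in either list. The rank of each peak is the authors' score within its own list and was used only to read their own intersection of both lists, 761 peaks. The depth per sample is unknown, since the tables give no counts.

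A gene was called when its q in the authors' comparison was at most 0.05. The 4sU table lists 1556 genes, all of them called in at least 1 of its comparisons, and the liver table lists 793 genes, all with a q of at most 0.0498 and a log2 fold change of at least 1 in size. The number of genes tested is not in these tables, so an overlap expected by chance, and counts adjusted over the list alone, are not given. The background of every gene test is therefore the other genes of the same table. No per-sample values were used, so no model was fitted and K1-NanER was not tested against K1-ER. The 4sU replicates of K1-ER and of K1-NanER are different clones; nothing in the labels says whether the K1 replicates or the livers of 1 group came from separate cultures or litters.

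The peak lists were compared by an overlap of at least 1 bp, using positions as the lists give them. Overlap under uniform placement was estimated by drawing Nan-KLF1 peak positions between the first and last peak of each chromosome, in 1000 seeded draws. Location, gene and central motif of each peak are those of the authors, whose nearest gene lies within 300 kb. In the lists 225 KLF1 and 196 Nan-KLF1 peaks have no gene, and in 19 and 5 the gene name is a number left by spreadsheet date conversion and was matched to no gene. A search of the mm9 sequence for CACCC elements had been planned; the mm9 genome was not used here, and the authors' central motif took its place. The tables carry no strand, so distances from peaks were measured to the nearest edge of the gene's locus and not to its start. Gene starts are printed 1 higher than in the tables, because 429 of 1416 loci with a RefSeq length match it as end minus start and 39 are 1 short.

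The 16 gene lists were written before the data were examined and were described by how many members rose and fell. The direction of a list was tested by a two-sided exact binomial test and against the rest of the table by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists with a called member (9 in K1-ER, 10 in K1-NanER and 14 in liver). Peak classes and genes with a peak were compared by 22 two-sided Fisher's exact tests, adjusted together, and the 4 tests of cell genes in liver were adjusted together. Intervals of shares are 95% Wilson intervals and cover counting error only; peaks and genes of 1 experiment are not independent replicates. Tests within 5 bins of locus length, each holding an equal number of genes of the table, permuted genes within each bin 100000 times, and 1.00e-05 is the smallest p these permutations can give. Odds ratios within bins are Mantel-Haenszel estimates, a form adopted after a first run of these tests, which left their calls as they were. The groups without change that share 1 control were simulated with a threshold of 3 standard errors.

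Genes were named by a rule set before the data were examined: Klf1, then per comparison the 8 largest rises and the 8 largest falls with at least 1 FPKM in the higher group, the 3 highest genes at 0 in a group, and up to 4 called members per list (all of them in short lists), without predicted genes. For peaks the rule takes the 5 with the highest fold per class and the strongest peak of up to 4 members per list. Some genes that the rule takes are not reported here. Genes named outside it are said to have been picked after their values were seen. Alternatives tried were a q of 0.01, a minimum fold change, a minimum level, the upper 50% of each peak list by fold, other overlap rules, other peak-to-gene distances, single genomic locations and tests within bins of locus length.

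The steps were tested on simulated data. Of 200 planted peaks 200 were recovered as shared and 0 of 800 unplanted ones were. The planted peaks were KLF1 peaks moved by less than a typical peak width, and the unplanted ones lay beyond the chromosome ends. Both outcomes were therefore fixed in advance, and this check says nothing of false sharing. A simulated excess of peaks at genes was called in 200 of 200 runs and no excess in 7 of 200. The permutation within length bins called 11 of 200 runs without a link. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.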

Results

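The series measured what the erythroid transcription factor KLF1, and the Nan mutant of its DNA-binding zinc fingers, bind and switch on in mouse red cell precursors. It holds 16 samples. Binding was measured by chromatin immunoprecipitation sequencing (ChIP-seq) with a KLF1 antibody in K1 cells, an erythroblast line without KLF1, that carried tamoxifen-inducible fusions of the oestrogen receptor (ER) with KLF1 (K1-ER) or with Nan-KLF1 (K1-NanER). Each factor had 1 ChIP library and 1 input library. New transcription was measured by sequencing RNA labelled for 1 h with 4-thiouridine (4sU) in 2 libraries each of K1-ER, K1-NanER and parental K1 cells. The K1-ER and the K1-NanER libraries came from different clones per the labels, and the K1 libraries from parental cells. Polyadenylated RNA was sequenced from 3 wild-type and 3 Nan/+ fetal livers at embryonic day 14.5, after removal of globin RNA. All levels are the authors' FPKM (fragments per kilobase, scaled to the mapped fragments of a library), given as 1 value per group with no replicate values, so no spread between replicates stands beside them. The depth of the libraries is unknown, since the tables give no counts. Gene positions are on build mm9.

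The first comparison asked which genes new transcription gained or lost when KLF1-ER was active. K1-ER cells made more new RNA of embryonic globins, of 9 genes of heme synthesis and iron uptake and of 10 red cell membrane genes than K1 cells. Hba-x, the embryonic alpha-like globin (chromosome 11, 32176600 to 32178115), went from the floor of 0.1 FPKM in K1 to 299.8 FPKM in K1-ER in the authors' deposited table. The embryonic beta-like globin Hbb-bh1 (chromosome 7, 110990152 to 110991676) rose from 123 to 4174 FPKM, a log2 fold change of 5.08, in the authors' deposited table. Beta-s, an adult-type beta globin allele, and Crip1, a LIM domain protein, stood at the floor in K1 and at 22.4 and 18.4 FPKM in K1-ER in the authors' deposited table. The authors' deposited table also put Klf10, a Kruppel-like factor (chromosome 15, 38224168 to 38230462), at 3.39 FPKM in K1 and 399 FPKM in K1-ER.

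The steepest rises outside the globins were of varied kind. Rrad, a small Ras-related GTPase (chromosome 8, 107151966 to 107155221), rose by 8.87 on the log2 scale, from 1.29 to 603 FPKM, in the authors' deposited table. Mid1ip1, a regulator of fatty acid synthesis, rose from 35.2 to 1351 FPKM in the authors' deposited table. Mxd3, a repressor that pairs with MAX, rose from 4.73 to 209 FPKM, and the chloride channel gene Clcn2 from 0.839 to 37.7 FPKM, in the authors' deposited table. Nyap1, a signalling adaptor, rose from 0.430 to 22.0 FPKM in the authors' deposited table. Esr1, whose ligand-binding domain the fusion carries, stood at 2.41 FPKM in K1 and 136 FPKM in K1-ER in the authors' deposited table. Klf1 itself has no row in the expression tables used here and was not analysed here.

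The steepest falls in K1-ER were those of single genes of varied kind. Osgin1, an oxidative stress response gene, fell from 145 to 17.9 FPKM, and Srxn1, which repairs oxidised peroxiredoxins, from 84.2 to 4.49 FPKM, in the authors' deposited table. The gap junction gene Gja1 fell from 14.7 to 0.687 FPKM and the efflux pump gene Abcc2 from 6.67 to 0.332 FPKM in the authors' deposited table. Zcchc3, Amacr, Zkscan17 and the histone gene Hist1h4c completed the 8 steepest falls above the floor, with log2 fold changes of -3.80, -3.75, -3.02 and -3.00 in the authors' deposited table. Bcl2, which blocks apoptosis, was at 7.74 FPKM in K1 and at the floor in K1-ER, as were Crabp2 from 3.27 FPKM and Mia from 3.25 FPKM, in the authors' deposited table.

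All called genes of 3 erythroid lists rose in K1-ER, which were 9 of 24, 10 of 38 and 9 of 31 members. All 9 called genes of heme synthesis and iron uptake rose, among them the heme pathway enzymes Alad, from 6.51 to 54.2 FPKM, and Alas2, from 5.81 to 25.6 FPKM, the transferrin receptor Tfrc, from 21.1 to 93.7 FPKM, and the mitochondrial iron importer Slc25a37, from 14.3 to 52.3 FPKM, in the authors' deposited table. All 10 called genes of the red cell membrane and cytoskeleton rose, among them Epb4.9 (dematin), from the floor to 8.54 FPKM, Add2 (adducin), from 12.2 to 64.3 FPKM, and the blood group gene Ermap, from 21.3 to 85.6 FPKM, in the authors' deposited table. All 9 called genes of erythroid transcription and signalling rose, among them Nfe2, a globin locus activator, from 8.07 to 148 FPKM, Lmo4 from 4.76 to 73.1 FPKM, Sox6, a silencer of embryonic globin, from 2.31 to 13.1 FPKM, the erythropoietin receptor Epor from 129 to 485 FPKM, and the red cell pyruvate kinase Pklr from the floor to 3.74 FPKM, in the authors' deposited table. For each of these 3 lists the direction differed from an even split by a two-sided exact binomial test, with an adjusted p of 0.0117 over 9 lists. Against the rest of the table, in which most genes also rose, Fisher's exact test gave an adjusted p of 0.383 for each.

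The other lists were varied. All 4 listed globin and chaperone genes rose (exact binomial adjusted p = 0.188), with Hbb-y from 20.8 to 89.1 FPKM and the globin chaperone Ahsp from the floor to 7.43 FPKM in the authors' deposited table. In the list of apoptosis, p53 and stress response, 9 of 10 called genes rose (exact binomial adjusted p = 0.0483; against the rest of the table, Fisher's exact test, adjusted p = 0.894), with the cell cycle inhibitor Cdkn1a from 4.82 to 51.3 FPKM, the death gene Bbc3 from 34.4 to 362 FPKM and Ddit3 from 54.6 to 192 FPKM in the authors' deposited table. The list's name covers genes of opposed action: the 1 member that fell was Bcl2. In the cell cycle list 5 of 6 called genes rose (exact binomial adjusted p = 0.246), with the cyclin Ccnd3 from 36.0 to 278 FPKM, E2f2 from 43.4 to 151 FPKM and the inhibitor Cdkn2d from 6.37 to 43.8 FPKM, while the mitotic kinase Plk1 fell from 142 to 71.2 FPKM, in the authors' deposited table. The 5 called members of the Kruppel-like factor list all rose (exact binomial adjusted p = 0.113), with Klf11 from 8.81 to 53.3 FPKM and Klf16 from 60.8 to 247 FPKM in the authors' deposited table. Of the 6 called immediate early genes 5 rose (exact binomial adjusted p = 0.246), with Junb from 143 to 865 FPKM and Ier2 from 43.7 to 205 FPKM, while Spred2 fell from 6.05 to 1.30 FPKM, in the authors' deposited table. The only called lymphoid gene was Cd79a, at the floor in K1 and 1.41 FPKM in K1-ER in the authors' deposited table.

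In all, 768 genes passed the authors' q of 0.05 in K1-ER, of which 589 (76.7%) rose and 179 fell in the authors' deposited table. The median log2 fold change was 1.89 for genes that rose and -1.51 for genes that fell in the authors' deposited table, which include 72 genes at the floor in K1 and 25 at the floor in K1-ER. Because clones were compared with parental cells, differences between clones are part of every value.

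The second comparison asked the same of Nan-KLF1-ER. K1-NanER cells also made more new RNA of embryonic globins and of Klf10 than K1 cells, and less of the histone genes Hist2h3b and Hist1h3e. The authors' deposited table put Hba-x at 281 FPKM, Hbb-y at 141 FPKM against 20.8 FPKM in K1, and Hbb-bh1 at 418 FPKM against 123 FPKM. Klf10 rose to 347 FPKM, Rrad to 116 FPKM and Mxd3 to 158 FPKM in the authors' deposited table. Esr1, whose ligand-binding domain the fusion carries, was at 70.3 FPKM in K1-NanER and 136 FPKM in K1-ER in the authors' deposited table. The fusion RNA may thus differ in level between the lines, which was not tested and limits every contrast of KLF1 with Nan-KLF1. Tex13, a testis gene on the X chromosome (137342846 to 137347972), and Cib2, a calcium-binding protein, were at the floor in K1 and at 13.7 and 17.2 FPKM in K1-NanER in the authors' deposited table. Lasp1, Kif1b, Trp53i13 and Abhd15 also rose steeply, with log2 fold changes of 4.88, 4.87, 4.88 and 4.76 in the authors' deposited table.

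Core histone genes and Osgin1 were among the steepest falls. Hist2h3b fell from 767 to 73.7 FPKM, Hist1h3e from 753 to 82.8 FPKM and Hist1h4a from 222 to 25.9 FPKM in the authors' deposited table. Osgin1 fell from 145 to 8.43 FPKM, Gja1 from 14.7 to 0.828 FPKM and Pacs1, a sorting protein gene, from 150.3 to 16.8 FPKM in the authors' deposited table. Abcc2 and Amacr had log2 fold changes of -4.55 and -3.04 in the authors' deposited table. The glutathione transferase gene Gsta3, the chemokine receptor gene Ccr8 and Tmem119 were at 3.18, 2.42 and 2.37 FPKM in K1 and at the floor in K1-NanER in the authors' deposited table.

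No list had a direction that passed correction over 10 lists in K1-NanER. Of the 4 called genes of heme synthesis and iron uptake 2 rose and 2 fell: Alas2 rose to 26.1 FPKM and Tfrc to 112 FPKM, while the ferritin light chain Ftl1 fell from 1033 to 325 FPKM and the biliverdin reductase Blvrb from 118 to 36.3 FPKM, in the authors' deposited table. Alad, at 7.33 FPKM, Slc25a37, at 21.5 FPKM, and Epor, at 139 FPKM, did not pass the test against K1 in the authors' deposited table. In the membrane list 6 of 7 called genes rose (exact binomial adjusted p = 0.312), with the surface antigen Cd24a from 51.3 to 261 FPKM, while the ankyrin gene Ank1 fell from 38.6 to 16.5 FPKM, in the authors' deposited table. All 4 called genes of erythroid transcription and signalling rose (exact binomial adjusted p = 0.312): the kinase Jak2 from 3.05 to 26.5 FPKM, Lmo4 to 26.1 FPKM, Sox6 to 10.4 FPKM and Nfe2 to 30.5 FPKM in the authors' deposited table. All 4 called cell cycle genes rose (exact binomial adjusted p = 0.312), with the cyclin Ccne2 (chromosome 4, 11118501 to 11181406) from 7.27 to 60.2 FPKM, the inhibitor Cdkn2c from 6.03 to 42.0 FPKM, Cdkn1a to 32.5 FPKM and the retinoblastoma gene Rb1 from 4.21 to 12.1 FPKM in the authors' deposited table.

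All 7 called Kruppel-like and Sp factors rose in K1-NanER (exact binomial adjusted p = 0.156), among them Klf2 from the floor to 3.18 FPKM, Klf6 from 2.86 to 12.8 FPKM and Klf11 to 46.8 FPKM in the authors' deposited table. In the list of apoptosis, p53 and stress response 8 of 11 called genes rose (exact binomial adjusted p = 0.357), with Bbc3 at 95.5 FPKM and Sesn1 from 3.54 to 20.2 FPKM, and 3 fell, namely Bax, which promotes apoptosis, from 87.8 to 36.0 FPKM, Trib3 from 55.4 to 16.4 FPKM and Chac1 from 28.5 to 7.62 FPKM, in the authors' deposited table. The 3 called globin genes and the 3 called immediate early genes, Jun, Junb and Nr4a1, all rose (exact binomial adjusted p = 0.357 for each list). The only called hepatocyte marker, Dlk1, fell from 3.01 to 0.651 FPKM, and the only called platelet marker, Vwf, from 5.13 to 1.99 FPKM, in the authors' deposited table. The interferon, macrophage, granulocyte, stem cell and endothelial lists had no member in the 4sU table.

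In all, 1178 genes passed in K1-NanER, of which 737 (62.6%) rose and 441 fell, with median log2 fold changes of 1.63 and -1.40 in the authors' deposited table. The direction of change in K1-NanER followed locus length: with the table split into 5 length bins of equal size, the share that rose was 40.1% in the bin of the shortest loci and 84.6% in that of the longest, against 73.8% and 73.5% in K1-ER.

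Both lines shared 390 called genes. Of these 289 rose in both, 100 fell in both, and 1, Fam89b, went opposite ways, named after its values were seen: it rose from 20.7 to 81.6 FPKM in K1-ER and fell to 6.06 FPKM in K1-NanER in the authors' deposited table. A further 378 genes were called in K1-ER alone and 788 in K1-NanER alone. Of genes called in K1-ER alone 83.1% had the same sign in both, and the 299 that rose had a median log2 fold change of 1.70 in K1-ER and 0.53 in K1-NanER, in the authors' deposited table. Of genes called in K1-NanER alone 94.5% had the same sign in both, and the 448 that rose had medians of 0.65 in K1-ER and 1.48 in K1-NanER, in the authors' deposited table. E2f2, which did not pass the test in K1-NanER, had opposite signs, at 151 FPKM in K1-ER and 26.0 FPKM in K1-NanER against 43.4 FPKM in K1 in the authors' deposited table.

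The same K1 libraries served both comparisons. Simulated groups without any change that shared 1 control gave a correlation of 0.50. They had the same sign in 97.0% of genes called in 1 comparison and in 100% of genes called in both. Shared signs alone therefore cannot show a shared effect. The observed 83.1% and 94.5% of genes called in 1 line lie under the simulated share. The simulation held only unchanged genes and says nothing of the size of changes or of the number called in both. K1-ER and K1-NanER were not tested against each other, and a gene called in 1 line alone is not shown to differ between them.

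**Figure D1:**
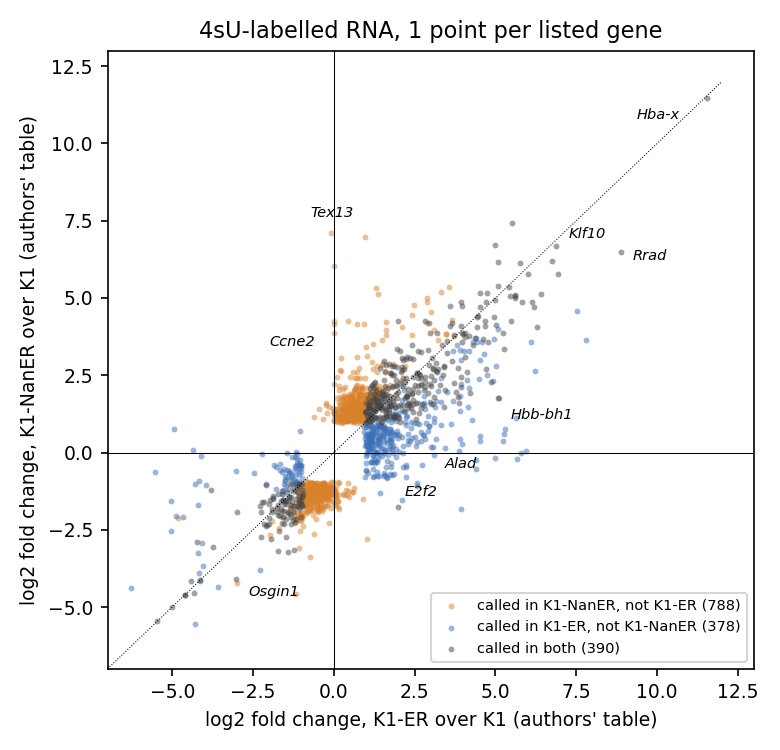
Each point is a gene of the 4sU table, with the authors' log2 fold change of K1-ER over K1 on the x axis and of K1-NanER over K1 on the y axis, coloured by the comparisons in which it was called (390 in both, 378 in K1-ER alone, 788 in K1-NanER alone); genes at 0 are plotted at the table's floor of 0.1 FPKM. Hba-x lies at 11.55 and 11.46, Hbb-bh1 at 5.08 and 1.76, and E2f2 at 1.79 and -0.74.

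The third comparison asked what 1 Nan allele does to fetal liver RNA. Nan/+ livers had more RNA of the embryonic globins Hba-x and Hbb-bh1, of Hamp, of Irf7 and of S100a8, and less RNA of 5 genes of erythroid transcription and signalling than wild-type livers. In the authors' deposited table Hba-x rose from 310.2 to 5717 FPKM and Hbb-bh1 from 429 to 4399 FPKM, both in libraries from which globin RNA had been removed. Hamp, the iron hormone hepcidin (chromosome 7, 31727388 to 31729036), rose from 1.08 to 41.5 FPKM, a log2 fold change of 5.26, in the authors' deposited table. Slco2b1, an organic anion transporter, rose from 0.390 to 19.5 FPKM in the authors' deposited table. Epb4.9 (chromosome 14, 71001991 to 71035855) fell from 84.8 to 7.98 FPKM and E2f2 (chromosome 4, 135728309 to 135751971) from 94.3 to 16.1 FPKM, log2 fold changes of -3.41 and -2.55, in the authors' deposited table.

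Further steep rises were those of Gng2, a G protein subunit, Klhl30, the zinc and iron transporter Slc39a14, the transcription factor Foxh1 and Pdzk1ip1, with log2 fold changes of 4.89, 4.83, 4.70, 4.60 and 4.52 in the authors' deposited table. Fam159b was listed at 0 in wild type and at 75.5 FPKM in Nan/+ in the authors' deposited table. The steepest fall was that of Xist, the RNA that silences 1 X chromosome in female cells, from 25.1 to 0.04 FPKM in the authors' deposited table. A difference in sex between the 2 groups of livers stays open and could be part of the liver values. Xist was followed by muscle genes: Myog fell from 5.00 to 0.06 FPKM, Myh3 from 3.51 to 0.03 FPKM, Tnnc2 from 4.69 to 0.16 FPKM, Actn2 from 2.27 to 0.08 FPKM, Actc1 from 21.5 to 1.08 FPKM and Acta1 from 6.59 to 0.34 FPKM in the authors' deposited table. Sln, another muscle gene, was at 2.91 FPKM in wild type and listed at 0 in Nan/+, and Nxpe2 fell from 89.0 to 3.00 FPKM, in the authors' deposited table.

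All 5 called genes of the erythroid transcription and signalling list fell in Nan/+ liver: E2f2, Pklr from 227 to 81.0 FPKM, E2f4 from 159 to 77.6 FPKM, Sox6 from 19.3 to 9.30 FPKM and Lmo2 from 181 to 89.9 FPKM in the authors' deposited table. Against the rest of the table this direction had an adjusted p of 0.0121 over 14 lists by Fisher's exact test, and 0.219 by the exact binomial test. Of the 4 called heme and iron genes 3 fell, the mitochondrial carriers Slc25a37 from 655 to 170.5 FPKM and Slc25a38 from 76.1 to 31.7 FPKM and the ferrireductase Steap3 from 72.1 to 30.7 FPKM, while the heme-degrading Hmox1 rose from 63.9 to 214 FPKM, in the authors' deposited table (Fisher's exact test, adjusted p = 0.112). Of the 6 called membrane genes 4 fell, Epb4.9, Slc2a4, Xpo7 and Tspo2, and the water channels Aqp1, from 45.7 to 145 FPKM, and Aqp8 rose in the authors' deposited table (Fisher's exact test, adjusted p = 0.0978). All 3 called cell cycle genes, E2f2, E2f4 and the phosphatase gene Cdc25b, fell (Fisher's exact test, adjusted p = 0.0686).

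All 18 listed granulocyte, mast cell and basophil genes rose, with the neutrophil proteins S100a8 from 180.1 to 1300 FPKM and Elane from 12.1 to 79.4 FPKM and the basophil proteases Mcpt8 from 0.620 to 6.80 FPKM and Prss34 from 0.190 to 1.48 FPKM in the authors' deposited table. All 15 listed interferon and hepcidin genes rose, with Irf7, a master regulator of the interferon response, from 4.74 to 61.4 FPKM, Ifitm3 from 33.0 to 149 FPKM and Zbp1 from 0.720 to 2.96 FPKM in the authors' deposited table. The exact binomial test gave adjusted p values of 1.07e-04 and 4.27e-04 over 14 lists for these lists. Against the rest of the table, in which 75.4% of genes rose, Fisher's exact test gave adjusted p values of 0.0686 and 0.0978. All 5 listed macrophage genes, among them Lyz1 from 9.19 to 33.4 FPKM, rose in the authors' deposited table (exact binomial adjusted p = 0.219).

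The remaining lists were short. Both listed globins rose, and so did both listed stem and progenitor genes, Gata2 and Cd48, and the lymphoid gene Cd79b from 2.83 to 7.27 FPKM in the authors' deposited table. Of 3 platelet genes Pf4, from 245 to 622 FPKM, and Gp1bb rose and Tubb1 fell from 55.2 to 22.5 FPKM in the authors' deposited table. In the apoptosis and stress list Hmox1 and the heat shock genes Hspa1a and Hspa1b rose, while Chac1 fell from 1.52 to 0.220 FPKM, in the authors' deposited table. The factor gene Sp4 fell from 8.55 to 4.25 FPKM, the cytokine-induced Cish rose from 6.0 to 25.8 FPKM and the phosphatase gene Dusp1 fell from 17.7 to 7.16 FPKM in the authors' deposited table. No hepatocyte and no endothelial marker was listed.

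In all, 793 genes were listed in liver, 598 higher and 195 lower in Nan/+, with median log2 fold changes of 1.37 and -1.32 in the authors' deposited table, which holds only genes with a log2 fold change of at least 1 in size. The share that rose depended on locus length: of 5 length bins, 91.8% of the genes rose in that of the shortest loci and 46.5% in that of the longest. Permutation within these 5 length bins gave a p of 0.138 for the granulocyte list, 0.135 for the interferon list and 0.121 for the heme list. It gave a permutation p of 0.0142 for the membrane list and 0.00189 for the list of erythroid transcription and signalling (all two-sided, not adjusted). The shortest bin ran from 0.334 to 3.19 kb and the longest from 37.6 to 567 kb. Length was thus matched only coarsely, and these p values are not free of it.

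**Figure D2:**
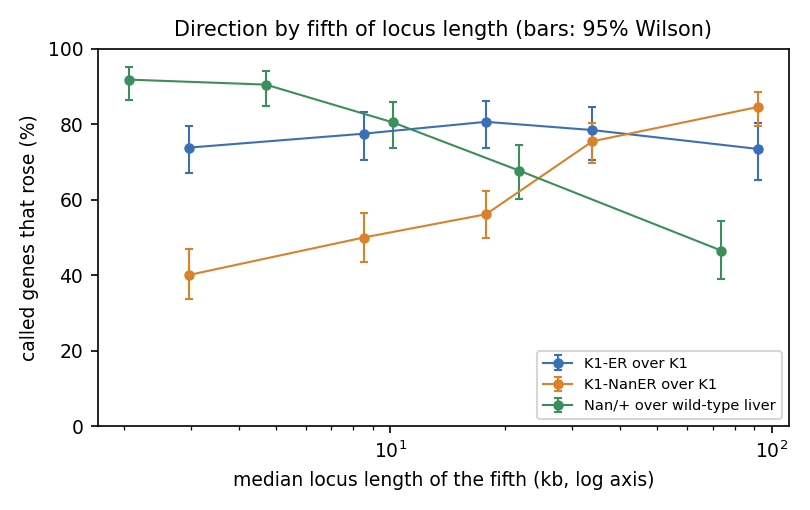
The share of called genes that rose (%) is plotted against the median locus length of each of 5 length bins (kb, log axis) for K1-ER, K1-NanER and Nan/+ liver, with 95% Wilson intervals as bars. From the shortest to the longest bin the share goes from 73.8 to 73.5% in K1-ER, from 40.1 to 84.6% in K1-NanER and from 91.8 to 46.5% in liver.

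Genes that rose in K1-ER cells were lower in Nan/+ liver more often than the other listed liver genes were. Of the 64 genes that rose in K1-ER and were listed in liver, 25 fell in Nan/+ (39.1%, 95% Wilson interval 28.1 to 51.3%), against 170 of the other 729 liver genes (23.3%), an odds ratio of 2.11. The two-sided Fisher's exact test gave p = 0.0093, or 0.0372 adjusted over 4 tests. Epb4.9, E2f2, Slc25a37, Slc25a38, Steap3, Pklr, Sox6 and Clcn2 were among the 25, while Hba-x and Hbb-bh1 rose in both. Other members, picked after their values were seen, were the water channel Aqp3 and Ache (acetylcholinesterase), which rose by 1.22 and 3.00 on the log2 scale in K1-ER and had log2 fold changes of -2.69 and -1.44 in liver in the authors' deposited table. For genes that rose in K1-NanER, 11 of 33 fell in liver (33.3%; Fisher's exact test, adjusted p = 0.445), for genes that fell in K1-ER 3 of 8 (adjusted p = 0.552 by Fisher's exact test), and for genes that fell in K1-NanER 5 of 27 (adjusted p = 0.649 by Fisher's exact test). At a q of 0.01 the odds ratio for genes that rose in K1-ER was 2.18 with a Fisher's exact p of 0.0739. Levels of the cell and liver tables were normalised separately and are not compared.

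The binding comparison asked where KLF1 and Nan-KLF1 sat on DNA. Fold enrichment is the authors' value for each peak and ranks peaks within its own list. The strongest shared peaks of the KLF1 list lay at the promoters of Esd, an esterase (chromosome 14, 75131628 to 75132574), and Zfp28, both at 1151-fold over input. The strongest shared peak of the Nan-KLF1 list was a distal one assigned to Fam19a3, at 1394-fold. At erythroid genes, KLF1 peaks shared with Nan-KLF1 lay at the promoter of Gata1, the master erythroid regulator (726-fold), at the promoter of Epb4.9 (437-fold), in an intron of E2f2 (347-fold), distal to Nfe2 (345-fold) and at the promoter of Klf10 (362-fold). KLF1 peaks without a Nan-KLF1 peak included those at the promoter of Foxo3, a regulator of red cell maturation (458-fold), distal to Hbb-y (248-fold) and in introns of Blvrb (227-fold), Slc25a38 (222-fold) and Alad (132-fold). Alad was not free of Nan-KLF1, which had a peak of its own elsewhere in an intron of the gene (97.5-fold). Nan-KLF1 peaks without a KLF1 peak included a distal one assigned to the corepressor gene Cbfa2t3 (732-fold), one at the promoter of the cadherin gene Cdh15 (546-fold), one in the coding sequence of Klf1 (chromosome 8, 87426389 to 87427532, 312-fold), and one at the promoter of the interferon-induced Isg20 (185-fold). The Klf1 peak had no central motif, and the K1-NanER cells carried an introduced fusion of Nan-KLF1. Whether the reads of this peak came from the Klf1 gene or from the DNA of the fusion was not tested.

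The KLF1 list held 5326 peaks and the Nan-KLF1 list 2758. Of the Nan-KLF1 peaks 1235 (44.8%, 95% Wilson interval 42.9 to 46.6%) overlapped a KLF1 peak by at least 1 bp, and of the KLF1 peaks 1215 (22.8%) overlapped a Nan-KLF1 peak. Random placement of the Nan-KLF1 peaks on the same chromosomes gave 8.08 overlaps on average and 21 at most in 1000 draws. These draws were uniform along each chromosome and ignored that peaks of both lists gather at promoters. An overlap above this level was thus largely fixed in advance and says little of the factors. Shared peaks were the stronger ones in each list, with median folds of 118 against 69.1 for KLF1 and 127 against 97.5 for Nan-KLF1. Each factor had 1 library and both lists stop at a fold of about 30, so a peak missing from a list can lie under its threshold. Folds repeated more in the Nan-KLF1 list, where the 10 most frequent values held 47.3% of peaks, against 14.9% in the KLF1 list. Depth or background may thus differ between the libraries, which was not tested. The numbers of peaks and of unshared peaks are therefore no measure of the factors alone. The share of overlap depended on the rule and ranged down to 27.6% by the authors' own intersection of summits.

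Nan-KLF1 peaks without KLF1 lay away from promoters. Promoters held 38.8% of shared Nan-KLF1 peaks, 26.6% of the 4111 KLF1-only peaks and 12.7% of the 1523 Nan-only peaks. The Nan-only share was lower than the KLF1-only share, with an odds ratio of 0.401 (two-sided Fisher's exact test, adjusted p = 3.08e-30 over the 22 peak tests). Intergenic sites held 9.92% of Nan-only and 4.60% of KLF1-only peaks (Fisher's exact test, adjusted p = 2.49e-12), distal sites 29.7% and 25.3% (Fisher's exact test, adjusted p = 0.00161) and introns 41.3% and 37.6% (Fisher's exact test, adjusted p = 0.0154).

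The central motifs differed between the peak classes. The authors' lists give each peak at most 1 of 18 forms of an 8-base CACCC-type element, in which bases 3, 4 and 5 vary. A motif was given for 78.6% of KLF1-only and 61.1% of Nan-only peaks. In KLF1-only peaks the leading forms were CCACGCCC (24.2% of peaks with a motif), CCCCGCCC (17.9%), CCACACCC (16.5%) and CCCCACCC (13.7%). In Nan-only peaks they were CCCTGCCC (26.2%), CCCAGCCC (22.0%), CCCCTCCC (12.2%) and CCCCGCCC (11.6%). The fourth base was A or T in 63.5% of the 930 Nan-only and 16.3% of the 3230 KLF1-only peaks with a motif, an odds ratio of 8.96 (two-sided Fisher's exact test, adjusted p = 1.51e-163). Shared peaks lay between, with 31.5% by the KLF1 summit and 36.2% by the Nan-KLF1 summit. A at the third base fell to 19.0% in Nan-only from 48.5% in KLF1-only peaks, and A at the fifth base to 6.56% from 32.8% (Fisher's exact tests, adjusted p = 2.51e-61 and 6.54e-68). Among promoter peaks alone the fourth base was A or T in 41.6% of Nan-only and 15.4% of KLF1-only peaks, an odds ratio of 3.92. Sequences were not searched here, so these shares rest on the authors' choice of motif forms and of 1 motif per peak.

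**Figure D3:**
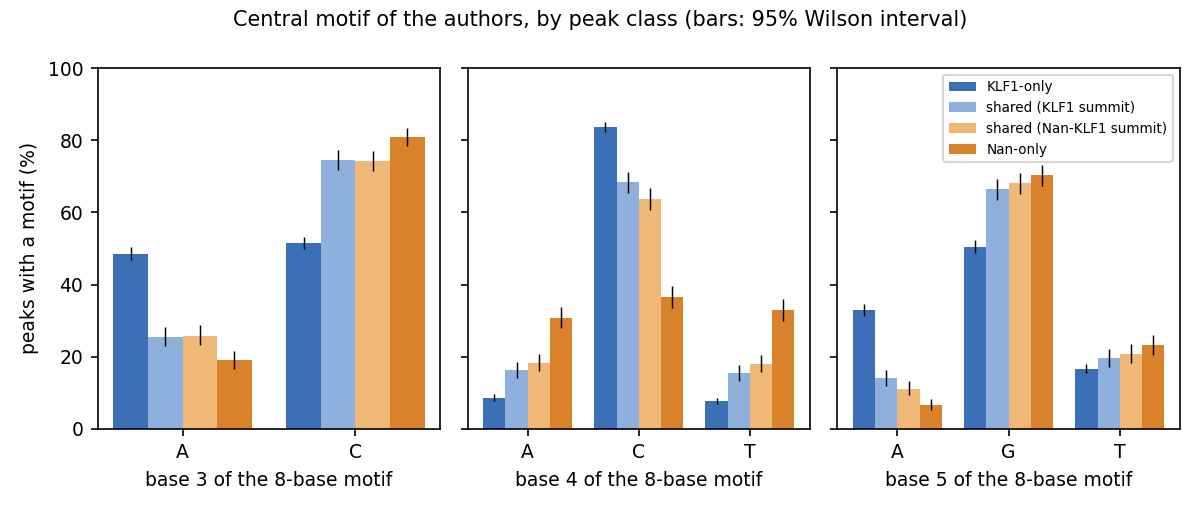
Bars give the share of peaks with a motif (%) that carry each base at positions 3, 4 and 5 of the authors' central 8-base motif, for KLF1-only, shared (by either summit) and Nan-only peaks, with 95% Wilson intervals. C at position 4 goes from 83.7% in KLF1-only to 36.5% in Nan-only peaks.

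Binding and transcription were then set side by side. Most genes that rose in K1-ER had a KLF1 peak by the authors' assignment: 71.1% of the 589 genes that rose in K1-ER, against 17.9% of the 179 that fell (odds ratio 11.3, two-sided Fisher's exact test, adjusted p = 1.01e-36). Among them were Klf10, Epb4.9, E2f2, Nfe2, Alad, Epor and Hbb-y. Nan-KLF1 peaks were assigned to 31.5% of the 737 genes that rose in K1-NanER and 12.5% of the 441 that fell (odds ratio 3.22, Fisher's exact test, adjusted p = 6.85e-14). With peaks within 20 kb of the locus this odds ratio was 1.48 (Fisher's exact p = 0.00217). Genes that rose in K1-ER had a Nan-KLF1 peak in 40.1% of those not called in K1-NanER and in 45.0% of those called in both (Fisher's exact test, adjusted p = 0.268). E2f2, with an intron peak of Nan-KLF1 at 107-fold, was one of those bound and not called in K1-NanER. Genes with a Nan-KLF1 peak and no KLF1 peak made up 7.14% of genes that rose in K1-NanER alone and 1.34% of genes that rose in K1-ER alone (odds ratio 5.67, Fisher's exact test, adjusted p = 2.31e-04). Their share was 4.15% among genes that rose in both (Fisher's exact test against K1-NanER alone, adjusted p = 0.129), and 7.26% and 5.44% among genes that fell in K1-ER and in K1-NanER. This class leaves out every gene with a KLF1 peak. Such genes made up 72.2% of those that rose in K1-ER alone, 69.9% in both and 39.7% in K1-NanER alone. The lower share of the class in K1-ER alone is thus partly built in and does not show binding particular to K1-NanER genes. Any Nan-KLF1 peak was less frequent among genes that rose in K1-NanER alone (22.8%) than among those that rose in both (45.0%; Fisher's exact test, adjusted p = 5.47e-10).

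In fetal liver, KLF1 peaks were assigned more often to genes that were lower in Nan/+ than to genes that were higher. A KLF1 peak was assigned to 36.4% of the 195 genes that fell, among them Epb4.9, E2f2 and Slc25a38, and to 21.2% of the 598 that rose (Fisher's exact test, adjusted p = 5.57e-05, odds ratio 2.12 for genes that fell). With peaks within 20 kb of the locus this odds ratio was 1.37, with a Fisher's exact p of 0.0633. Nan-KLF1 peaks were assigned to 13.8% of genes that fell and 16.1% of those that rose (Fisher's exact test, adjusted p = 0.520). The peaks come from cell lines, not from liver. Among the fixed lists, 15 of 24 heme and iron genes, 21 of 38 membrane genes and 19 of 31 genes of erythroid transcription and signalling had a KLF1 peak, and 7, 14 and 14 had a Nan-KLF1 peak. Of the 31 interferon and hepcidin genes 3 had a KLF1 and 2 a Nan-KLF1 peak, and of the 22 granulocyte and mast cell genes 2 had a KLF1 and 2 a Nan-KLF1 peak.

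**Figure D4:**
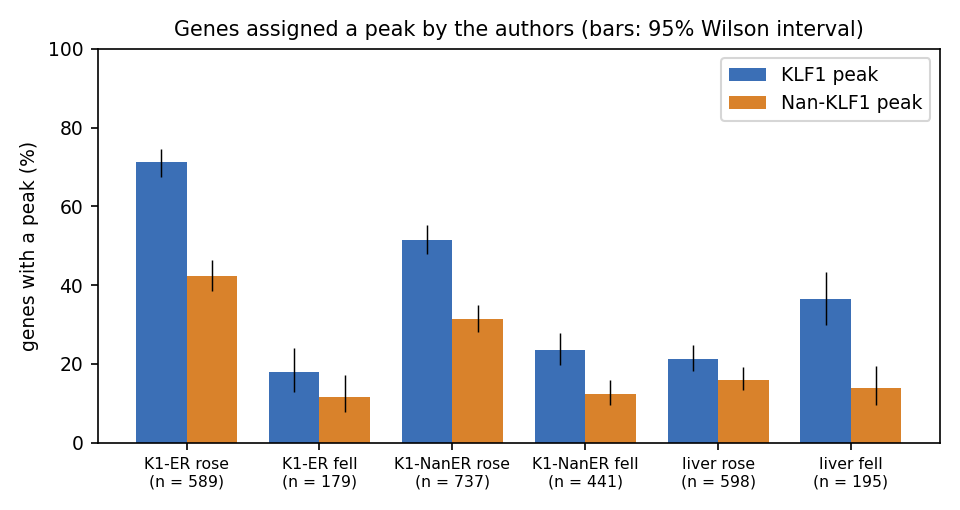
Bars give the share of genes (%) to which the authors assigned a KLF1 or a Nan-KLF1 peak, for genes that rose or fell in K1-ER, K1-NanER and Nan/+ liver, with 95% Wilson intervals and the number of genes under each group. KLF1 peaks reach 71.1% in genes that rose and 17.9% in genes that fell in K1-ER, and 21.2% and 36.4% in liver.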

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

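Of 54 alternatives, 37 kept the direction and the side of the threshold or left a count close to the main one. A further 5 lost the threshold, 11 moved and 1 reversed. The 37 include settings that removed no gene and so tested nothing. The minimum level kept all 768 K1-ER, 1178 K1-NanER and 793 liver genes, and the minimum fold change kept all 793 liver genes. Of the 54, 28 were planned before the data were examined and 26 were added after seeing them. Added were the tests within bins of locus length, the gene-to-peak distances of 20 kb and 1 kb measured from the locus, the motif within single locations, the authors' intersection, and the liver count without Xist and the muscle markers (780 genes) or without the bin of the shortest loci (634 genes).

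A q of 0.01 left 462 called genes in K1-ER, 638 in K1-NanER, 220 in both and 377 in liver, as a stricter threshold must. It left the odds ratio of K1-ER genes that fell in liver at 2.18 with a Fisher's exact p of 0.0739, where fewer genes were tested. Over the alternatives of that result the exact or permutation p ran from 0.00572 to 0.0739. The upper 50% of each peak list by fold held 2663 KLF1 and 1379 Nan-KLF1 peaks by construction.

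The share of Nan-KLF1 peaks with a KLF1 peak, 44.8% at 1 bp, was 41.8% for the upper 50% of both lists, 29.5% with a reciprocal overlap of 50%, 35.7% with summits within 100 bp, 31.9% with equal numbers of peaks and 27.6% by the authors' intersection of summits; each of these rules admits fewer pairs.

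KLF1 peaks at liver genes that fell lost the threshold with peaks within 20 kb of the locus (odds ratio 1.37, Fisher's exact p = 0.0633; range over the alternatives of this result 1.50e-05 to 0.0633). Nan-KLF1 peaks at liver genes changed side with peaks within 1 kb of the locus, from an odds ratio of 0.840 to 1.04, neither past the threshold (Fisher's exact p = 0.496 and 0.905). In both cases the cause was not tested. Within bins of locus length the granulocyte, interferon and heme lists in liver lost the unadjusted threshold against other genes. The location of peaks, the fourth base of the motif, KLF1 peaks at K1-ER genes and Nan-KLF1 peaks at K1-NanER genes kept direction and threshold under each alternative run for them, with odds ratios of 0.508 for location, 3.92 to 12.9 for the motif, 11.4 to 15.7 for KLF1 peaks and 1.48 to 3.25 for Nan-KLF1 peaks.

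No paired analysis was possible because the tables carry 1 value per group. For the same reason another pseudocount, another normalization, a count filter, a replicate block, leaving out a replicate and the contrast of K1-NanER with K1-ER were not run. Promoters defined by 1 kb to the gene start and motifs within 50 bp of the summit were not run either, since strand and sequence were not used here. Depth is unknown; it limits weak peaks, which can be missing from 1 list, and genes near the floor.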

Other observations

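The tests of the gene families, of length bias between the liver libraries, of the mitochondrial genes as a class, of sex, of muscle, of weak peaks and of the base preference at shared sites were chosen only after the result was seen.

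Most called histone genes, largely replication-dependent ones such as Hist1h3e and Hist1h1c, fell in each cell line, in comparisons that share the K1 libraries. In K1-ER 29 of 30 called histone genes fell, with a median log2 fold change of -1.47 in the authors' deposited table (Fisher's exact test against other called genes, adjusted p = 8.49e-18 over 5 families, which describes a set chosen after the tables had been seen). In K1-NanER 30 of 34 fell, with a median of -1.92 in the authors' deposited table (Fisher's exact test, adjusted p = 1.77e-09). Within 5 bins of locus length the permutation p was 1.00e-05, the smallest these permutations can give, in K1-ER and 2.30e-04 in K1-NanER. The bin of the shortest loci ran from 0.275 to 5.60 kb, with a median of 2.97 kb, so genes within it still differed in length. In K1-NanER, where direction followed length, this test cannot separate the histone genes from other very short loci. Simulated groups without change that shared 1 control gave the same sign in 100% of genes called in both, so the agreement of the 2 lines does not count as a second observation.

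A search of gene names for the mitochondrial respiratory chain, import and mitochondrial ribosome found 46 genes in the liver table, and all 46 rose, with a median log2 fold change of 1.28 in the authors' deposited table, among them Ndufa13, Ndufb7, Uqcr11 and Timm13. The same search, which also takes cytosolic ribosomal protein genes, found 26 called genes in K1-NanER, 11 of them cytosolic ribosomal, and 0 cytosolic ribosomal genes in liver. Of these 26 genes 21 fell, with a median of -1.43 in the authors' deposited table. Only 5 genes are in both sets. The family was defined after the tables had been seen and narrowed once, and members that were not called are not in the tables, so nothing is said here of the class as a whole.

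The direction of change followed locus length in liver and, the opposite way, in K1-NanER. Among liver genes outside the fixed lists and the mitochondrial family, the share that rose was 44.5 percentage points higher in the shortest than in the longest of 5 length bins (95% interval 35.3 to 53.6; 93.8% of 113 against 49.3% of 150), which leaves a length bias between the libraries open. The mitochondrial family does not account for this trend, since the difference was 44.3 points among all genes outside it (95% interval 35.2 to 53.4). A length bias between the 4sU libraries cannot be told apart from an effect of the mutant: the K1-NanER over K1-ER log2 ratio of genes called in K1-ER alone was 0.79 higher in the longest than in the shortest bin (95% interval 0.45 to 1.52), but both comparisons selected these genes and 0 genes of the table were called in neither. More listed peaks at long genes do not account for the K1-NanER trend: among K1-NanER genes without a peak the share that rose was still 55.6 points higher in the longest bin (95% interval 45.1 to 66.0). Peaks under the threshold, or assigned to another gene, are not seen by this test, so unlisted binding at long genes stays open. Values per library were not used here.

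Xist and muscle genes were lower in Nan/+ liver. A list of 38 muscle genes, of which 1 is also in a fixed list, had 12 members in the liver table and all 12 fell, the most abundant being Actc1 at 21.5 and Acta1 at 6.59 FPKM in wild type in the authors' deposited table, so muscle tissue in some wild-type samples is a candidate source; whole fetal liver was used with no sorting step that would remove it, and how many of the other 26 markers liver expresses is unknown. Of the other 15 listed X-linked genes 53.3% rose, against 75.9% of 777 autosomal ones (one-sided Fisher's exact p = 0.986). Only genes with a log2 fold change of at least 1 in size are listed, so smaller rises of X-linked genes are missing. The test therefore cannot decide whether a second X chromosome was active, and a difference in the sex of the livers stays open. No Y-linked gene (0) is listed, which such a difference could have brought up, but a missing gene excludes nothing in a table of called genes. A loss of Xist and of muscle RNA caused by the Nan allele was not tested.

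Nan-KLF1 peaks without a KLF1 peak carried other central motifs, with A or T at the fourth base in 63.5% (66.7% of the 18 forms have A or T there), while C at the third base (81.0%) and G at the fifth (70.3%) prevailed. The share with A or T at the fourth base was not higher at low fold. Of 4 bins of fold, the lowest held 60.9% and the highest 67.8%, a difference of -6.87 percentage points (95% interval -15.5 to 1.81). As 10 fold values hold 47.3% of Nan-KLF1 peaks, tied folds were also kept together, which gave -8.50 points (95% interval -17.3 to 0.274). The fold is a ratio over input and reads per peak are not given. These bins therefore cannot tell whether peaks near the background carry such forms. The difference from KLF1-only peaks held within introns alone, with an odds ratio of 9.81 (95% interval 7.64 to 12.6). Among promoter peaks the odds ratio was 3.92, so the class of location changed its size without accounting for all of it. Base composition around the summits was not measured and stays open. At shared sites where both summits had a motif, 170 of 907 pairs differed at the fourth base, and the Nan-KLF1 summit held the A or T in 102 of them and the KLF1 summit in 68 (two-sided exact binomial p = 0.0112), which is consistent with a changed base preference of the Nan protein, be it a loss of the preference for C or a gain for A or T. Motif forms met by chance were not tested, and 1 library per factor and the authors' choice of forms stand behind these shares, so this remains a hypothesis.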
